A study of Mus musculus with 20 samples.

How the data were processed

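The data were RNA sequencing of sorted bone marrow cells and of whole bone marrow from male 129S4 mice, wild-type or Fancd2-/-. Per the labels, mice ate a diet with 300 mg/kg oxymetholone or placebo for 3 months from weaning and were 4 months old when the marrow was taken. KSL cells were cKit+ Sca1+ Lin- cells sorted in 2 rounds by FACS, in pools of 5 mice, and erythroblasts were Ter119+ CD71-high FSC-high cells of 1 mouse per library. There were 3 libraries in each of 4 KSL groups (Fancd2-/- or wild-type, oxymetholone or placebo) and in each of 2 wild-type erythroblast groups, and 1 whole bone marrow library of each genotype on placebo. Per the labels, libraries were made with TruSeq and sequenced as 51-base reads on a HiSeq, aligned with Bowtie to mm9 and analysed with edgeR. The versions of these tools, the strand of counting and the handling of reads with several matches are not given in the sources used here. Fancd2-/- erythroblasts were not analysed here.

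The deposited table gave reads as counts for 26005 RefSeq transcripts in 20 libraries, and all 20 libraries were used. For each of 20377 gene symbols the transcript with the largest total count was kept, because isoforms of a gene share reads. The design text pairs a KSL library whose name occurs in no sample label. It was taken as the Fancd2-/- placebo sample with the closest name, replicate 1. Levels are counts-per-million (CPM) computed from the deposited counts with TMM normalisation, and changes are log2 fold changes. The deposited normalised matrix holds a score, per the authors the counts of each library scaled to a total of 20 M reads and rounded, and it served only as an alternative (limma on log2 of the score plus 1). Gene positions are those of mm9, from the RefSeq gene table of that build.

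Genes were tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 after filterByExpr, with Benjamini-Hochberg adjustment over the genes tested and a call at adjusted p under 0.05. Every adjusted p of a gene is from edgeR unless another tool is named. Oxymetholone in KSL cells was tested with a block for the pair of libraries that, per the labels, shared a flow cytometer setting. All 12 KSL libraries entered that fit, which also gave the genotype by oxymetholone interaction and the mean of both oxymetholone effects. Genotype is constant within a pair, so it was tested with group means over the 12 KSL libraries. Erythroblasts (6 libraries), erythroblasts against KSL on placebo (6 libraries) and the difference of the oxymetholone effect between these populations (12 wild-type libraries) were tested with group means. In whole bone marrow, with 1 library per genotype, only ratios with 95% intervals for counting error were computed, and lists were placed among 10000 random lists matched for expression. Levels are given as mean ± SD, with n = 3 libraries per group, and log2 changes as estimate ± SE.

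The genes named were the 12 with the smallest p in each direction among called genes. A named gene also needed the same sign in each pair, or groups that did not overlap, and a mean of at least 1 CPM. Groups of 3 that do not overlap arise by chance in 10% of unchanged genes. With fewer than 5 calls, the 5 genes with the smallest p in each direction are given as a ranking. Fancd2, the targeted gene, and Spp1, named in the series title, were followed in every comparison. In whole bone marrow up to 10 genes per direction with at least 100 counts in a library were named. Up to 4 members of a called list were named. Some genes that met these rules are not reported.

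The lists of genes were written from general knowledge and tested with camera in limma 3.58.1 (correlation preset to 0.01, prior count 2), against all other genes and with adjustment over the lists of a comparison. camera with an estimated correlation and fry were run beside it. The 27 lists were G2/M and mitosis, DNA replication, cell cycle inhibitors and quiescence, haematopoietic stem cell genes, lymphoid-primed progenitor genes, osteopontin and its receptors, niche adhesion and homing, steroid receptor targets, telomerase and shelterin, the Fanconi pathway, p53 targets, TNF and NF-kB response, interferon response, oxidative stress response, TGF-beta signalling, immediate early genes, heme synthesis and iron, erythroid, neutrophil granule, monocyte and macrophage, B cell, T and NK cell, megakaryocyte, mast cell, basophil and eosinophil, stromal and ribosomal protein genes, and a male and female check. A list of 26 fibroblast genes was added after the data were seen. Hba-a1 and Hba-a2, like Hbb-b1 and Hbb-b2, share reads, and counts of ribosomal protein genes are uncertain because processed copies share their sequence.

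The tests, lists and most alternatives were chosen before the data were examined. These alternatives were median-of-ratios size factors, no low-count filter, DESeq2 1.42.0, limma voom with sample quality weights, each library or pair left out, no block, the 6 libraries of a genotype alone, both wild-type populations together for the erythroblasts, the scaled matrix, a rule of 1.5-fold the same way in each of 3 pairs, and genes of at least 10 CPM in the correlations. Chosen after seeing the data were removal of each library's trend on transcript length and GC (splines with 4 degrees of freedom), all RefSeq entries, a term for 2 sets of erythroblast libraries, and the lists without Fancd2-/- placebo replicate 3. A test of the genotype difference in pairs left out was also added then, in which a pair of each genotype was left out in 9 ways. The 170 genes with the smallest p between genotypes on placebo were chosen in the other libraries. Their log2 CPM was compared in the libraries left out. Transcript length and GC came from the longest GENCODE protein-coding transcript of each symbol, which need not be the RefSeq transcript counted. They matched 19841 of 20377 symbols (97.4%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

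The procedure was tested on simulated counts with the depth and spread of these libraries, with 200 genes changed. It recovered 56.7% of genes changed 2-fold and 96.9% of those changed 4-fold between genotypes on placebo, and 64.6% and 92.4% for oxymetholone in Fancd2-/- pairs. For the interaction it recovered 29.2% at 2-fold and 81.5% at 4-fold. A changed list was called in 9 of 9 simulated comparisons, also with an estimated correlation, and an unchanged list in 2 of 231 (0 with an estimated correlation). Simulated genes were drawn independently of each other, so these list counts say nothing about lists whose members are correlated.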

Results

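The KSL libraries held 10.8 M to 121 M counted reads (11.3-fold), the erythroblast libraries 17.2 M to 20.8 M and the whole bone marrow libraries 100 M and 107 M. Ddx3y, a gene of the Y chromosome, was at 25.4 to 101 CPM in all KSL libraries, as in male animals. Lowest was Fancd2-/- placebo replicate 3 at 25.4 CPM, and next lowest wild-type placebo replicate 1 at 43.3 CPM. Uty, Eif2s3y and Kdm5d, also of the Y chromosome, were lowest in Fancd2-/- placebo replicate 3 too (8.9, 32.5 and 15.6 CPM). That library also stood apart on the first principal component of the KSL libraries, with a score of 66.9 against -23.5 to 4.5 in the other 11. Long transcripts were low in it, with a slope of -0.251 log2 units per doubling of transcript length against -0.045 to 0.108 in the other 11, which leaves the quality of its RNA or library in doubt.

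Fancd2 (NM_001033244, chr6:113481676-113546279, mm9), which encodes the protein that FANCI pairs with at stalled replication forks, fell to 6.59 to 8.73 CPM in the 6 Fancd2-/- KSL libraries from 16.8 to 23.5 CPM in the 6 wild-type ones. The log2 difference was -1.30 ± 0.18 on placebo (7.78 ± 0.63 against 19.2 ± 2.93 CPM, n = 3 each, edgeR adjusted p = 0.00514) and -1.50 ± 0.18 on oxymetholone (7.32 ± 1.22 against 20.5 ± 2.80 CPM, adjusted p = 0.00531). In whole bone marrow it was at 7.10 CPM in the Fancd2-/- library and 26.2 CPM in the wild-type one (ratio 0.271, counting interval 0.25 to 0.294). Wild-type erythroblasts had 105 ± 3.92 CPM on oxymetholone and 99 ± 3.94 CPM on placebo. The genotype labels of all 12 KSL libraries fitted these levels, and the remaining reads in Fancd2-/- cells were not traced to exons.

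On placebo, Fancd2-/- KSL cells carried more mitotic transcripts than wild-type ones. Ccnb1 (NM_172301, chr13:101548694-101556441), which encodes cyclin B1, rose from 24.1 ± 5.35 to 50.5 ± 5.74 CPM (log2 1.07, edgeR adjusted p = 0.0109), and with it Ccnb2 (0.91, adjusted p = 0.00602), Ube2c (1.16, adjusted p = 0.014), Cenpa (0.88), Cdc25c (0.96) and Cdk1 (0.87, adjusted p = 0.0206). Socs2 (NM_007706, chr10:94874124-94879491), a brake on cytokine signalling, rose from 48.6 ± 3.17 to 125 ± 18.9 CPM (1.36 ± 0.19, adjusted p = 0.00514), and Cd48, which stem cells lack and more mature progenitors carry, from 154 ± 18.7 to 301 ± 35.7 CPM (0.97 ± 0.13, adjusted p = 0.00514). Tpm4 (0.94), Clec4e (1.03), D2Ertd750e (0.86) and the noncoding 6530418L21Rik (2.12, 2.67 against 0.604 CPM) rose too. With some single libraries left out, Ube2c, Cdc25c, Cdk1, Tpm4, Clec4e, D2Ertd750e and 6530418L21Rik lost their calls. Ccnb1, Ccnb2, Cenpa, Socs2 and Cd48 kept theirs with any library left out.

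Ndn (NM_010882, chr7:69493163-69494813), an imprinted gene that restrains stem cell division, fell from 65.5 ± 8.12 to 28.1 ± 1.82 CPM in Fancd2-/- placebo cells (log2 -1.22 ± 0.14, edgeR adjusted p = 0.00265). Pde2a, a cyclic nucleotide phosphodiesterase (NM_001143849, chr7:108599766-108661341), fell from 77.9 to 31.2 CPM (-1.32 ± 0.16, adjusted p = 0.00265) and the matrix protease gene Mmp2 from 58.9 to 30.6 CPM (-0.95). Rnf208 (-1.67), Tenc1 (-1.31), Rtkn (-1.09), Tinagl1 (-1.40), Rhbdf1 (-1.49), Gria3 (-1.20), Plag1 (-1.86) and Cntn1 (-2.13) also fell. Among stem cell genes Prdm16 fell by 0.73 log2 units (adjusted p = 0.0383).

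In all, 170 of 13259 genes differed between genotypes on placebo, 67 higher and 103 lower in Fancd2-/- cells. DESeq2 called 815 and limma voom 1468. The split of directions depended on scaling, with 222 higher and 152 lower after removal of the length and GC trends, and 48 higher and 121 lower on the scaled matrix. Leaving out a library lowered the count, to 34 without Fancd2-/- placebo 2 (32 of the 170 kept), 76 without Fancd2-/- placebo 3 (62 kept), and 19, 30 and 31 without wild-type placebo 1, 2 and 3 (19, 30 and 30 kept). Without Fancd2-/- placebo 1 it was 236 (123 kept).

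**Figure D1:**
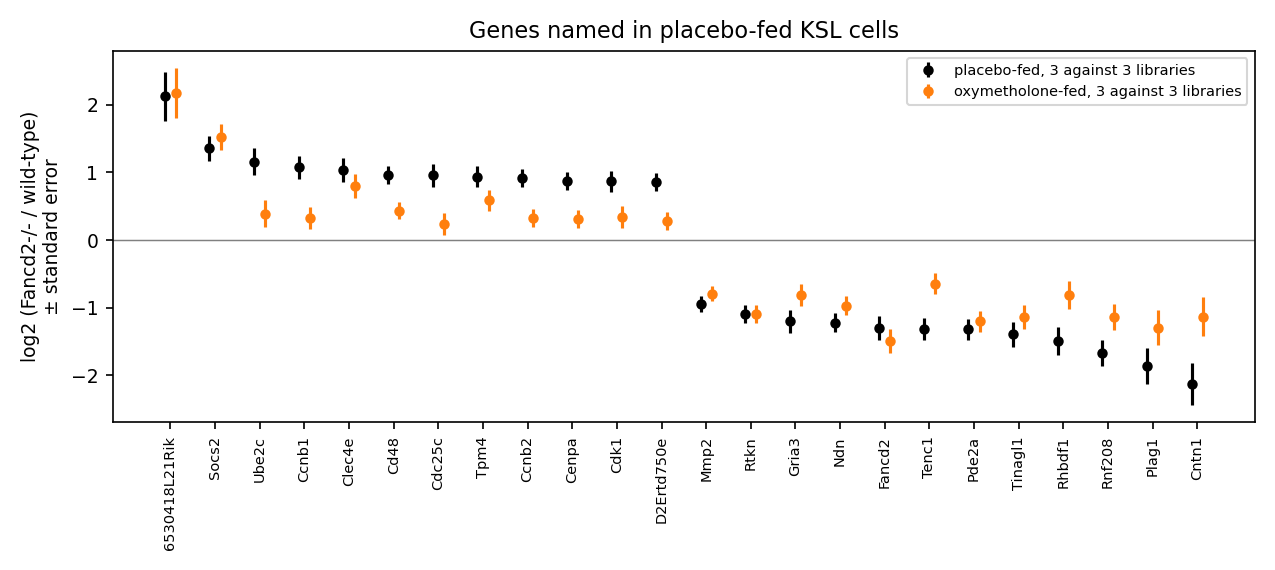
Log2 ratio of Fancd2-/- over wild-type KSL cells (vertical axis, ± SE, 3 against 3 libraries) of the 24 genes named on placebo. Black points are placebo-fed and orange points oxymetholone-fed mice, with Fancd2 at -1.30 and -1.50.

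As a group the 25 G2/M and mitosis genes rose in Fancd2-/- placebo cells (median log2 0.70, 25 of 25 above 0, camera adjusted p = 7.8e-21, adjusted p = 0.265 with an estimated correlation). Of them 11 were called over all genes and 21 when adjusted over the list alone. The 26 DNA replication genes rose by a median of 0.41 (camera adjusted p = 9.53e-11, adjusted p = 0.265 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at 0.66 (edgeR adjusted p = 0.0257) the only call over all genes and 13 adjusted over the list alone. The 25 haematopoietic stem cell genes fell (median -0.45, 23 below 0, camera adjusted p = 1.36e-07, adjusted p = 0.265 with an estimated correlation), with 2 called over all genes and 14 lower and 1 higher adjusted over the list alone. Called by camera were also oxidative stress genes (0.26, camera adjusted p = 0.00268, adjusted p = 0.265 with an estimated correlation), TGF-beta signalling (-0.21, 0.0122, 0.418), TNF response (-0.27, 0.0214, 0.341), ribosomal protein genes (0.16, 0.0214, 0.534), mast cell and basophil genes (1.11, 0.0214, 0.281) and megakaryocyte genes (-0.42, 0.0373, 0.281) (median, camera adjusted p, and adjusted p with an estimated correlation). Of these 9 lists 5 were called without Fancd2-/- placebo 3 (mitosis 0.59, DNA replication 0.25, stem cell genes -0.31, oxidative stress 0.14 and mast cell genes 1.10). With the length and GC trends removed 5 were called too (mitosis 0.71, DNA replication 0.40, stem cell genes -0.34, TNF response -0.20 and oxidative stress 0.14).

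In oxymetholone-fed mice the genotypes differed in 17 of 13259 genes, 4 higher and 13 lower in Fancd2-/- KSL cells. Socs2 was again higher (log2 1.52 ± 0.19, edgeR adjusted p = 0.00531), as were Slamf1 (NM_013730, chr1:173697263-173731315), the stem cell marker CD150 (1.07, adjusted p = 0.0316), Cfp, the complement factor properdin (0.96, adjusted p = 0.0382), and 6530418L21Rik (2.18, adjusted p = 0.0392). Pde2a (-1.20), Ndn (-0.97), Mmp2 (-0.79), Rtkn (-1.10), Tinagl1 (-1.13) and Rnf208 (-1.14) were again lower, and with them the actin bundler gene Fscn1 (-1.97, adjusted p = 0.0274), Rcor2 (-0.82), Htra3 (-1.63), Fam83h (-1.65) and the syndecan gene Sdc1 (-0.90, adjusted p = 0.0473). Of these calls, 8 were left without Fancd2-/- oxymetholone 1, 3 without 2 and 5 without 3 (6 called), and 5, 2 and 3 without wild-type oxymetholone 1, 2 and 3. DESeq2 called 86 genes and limma voom 47.

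Of the 170 genes called on placebo 169 had the same sign on oxymetholone (99.4%) and 160 were closer to 0, with a median size of 0.86 on placebo and 0.44 log2 units on oxymetholone. Genes chosen for their size on placebo shrink in any other libraries. With genes chosen on placebo in the other pairs instead, the pairs left out had a median of 0.61 on placebo and 0.35 on oxymetholone. It was smaller on oxymetholone in 9 of 9 ways of leaving out a pair of each genotype, which share libraries. That choice rested on placebo libraries alone and so favoured genes whose difference is larger on placebo. Genes were not chosen on oxymetholone for comparison. Called in both diets were 15 genes, 3 higher (0.0202 by chance) and 12 lower (0.101 by chance). These chance values assume independent comparisons, while the oxymetholone-fed libraries are pair partners of the placebo-fed ones. The p53 target genes, which respond to DNA damage, were higher in Fancd2-/- cells on oxymetholone (median 0.25, 16 of 20 above 0, camera adjusted p = 3.2e-05, adjusted p = 0.0434 with an estimated correlation), led by Eda2r (1.70), Phlda3 (1.57) and Zmat3 (0.89). Of its members 3 passed when adjusted over the list alone and 0 over all genes. It was the only list of any comparison kept with an estimated correlation, but that call was lost with the length and GC trends removed (median 0.24, adjusted p = 0.169 with an estimated correlation), and fry called 0 lists here. On placebo the same list had a median of 0.23 (camera adjusted p = 0.0515). Mitosis genes stayed higher on oxymetholone at 0.22 (camera adjusted p = 1.28e-06, adjusted p = 0.67 with an estimated correlation), DNA replication genes at 0.13 (camera adjusted p = 0.00476), and stem cell genes lower at -0.15 (camera adjusted p = 0.0132), with erythroid (0.23, 0.0445) and mast cell genes (0.52, 0.0446) higher, all lost with an estimated correlation.

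In Fancd2-/- KSL cells oxymetholone changed 0 of 13259 genes by edgeR (903 with unadjusted p under 0.05 against 663 by chance, smallest adjusted p = 0.688). Other labellings that parted all 3 pairs gave 712, 1563 and 1280 such genes, so the 903 did not stand out. DESeq2 and limma voom called 0 as well, and 16 genes passed without the low-count filter. The ranking was led by the chromatin remodeller gene Atrx (log2 0.64), Ankrd12 (0.71), Ccdc88a (0.66), BC005561 (0.60) and Tbkbp1 (0.47) upward. Downward it held Amotl1 (-5.69, 10.5 CPM in Fancd2-/- placebo 3 and at most 0.316 CPM in the other placebo libraries of that genotype), Rhou (-4.26), Fez1 (-4.14), Plbd1 (-1.23) and Serpina3f (-0.87). Without pair 1 or pair 2 the fit called 12 genes each. Atrx, Ankrd12 and Ccdc88a are long transcripts (10269, 8991 and 9376 bases), and long transcripts were low in Fancd2-/- placebo 3.

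Spp1 (NM_009263, chr5:104864137-104870069) encodes osteopontin, a matrix protein that limits the stem cell pool. It was at 13.3, 13.9 and 561 CPM in Fancd2-/- placebo KSL libraries 1 to 3 and at 16.1, 13 and 5.52 CPM in their oxymetholone partners. The log2 change of -1.68 ± 1.96 (edgeR adjusted p = 0.814) came from pair 3, and Spp1 was higher with oxymetholone in 1 of 3 pairs. In wild-type cells it was at 34.2, 5.81 and 6.69 CPM on placebo and 7.99, 6.66 and 8.99 CPM on oxymetholone (-0.55 ± 1.66, adjusted p = 0.999). The difference of the oxymetholone effects was -1.12 ± 2.59 (adjusted p = 0.972), and the genotype difference 3.64 ± 1.43 on placebo (adjusted p = 0.211) and 0.52 ± 1.39 on oxymetholone (adjusted p = 0.999). A lower Spp1 with oxymetholone was therefore not established in KSL cells, and no Spp1 change passed a test within them.

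**Figure D2:**
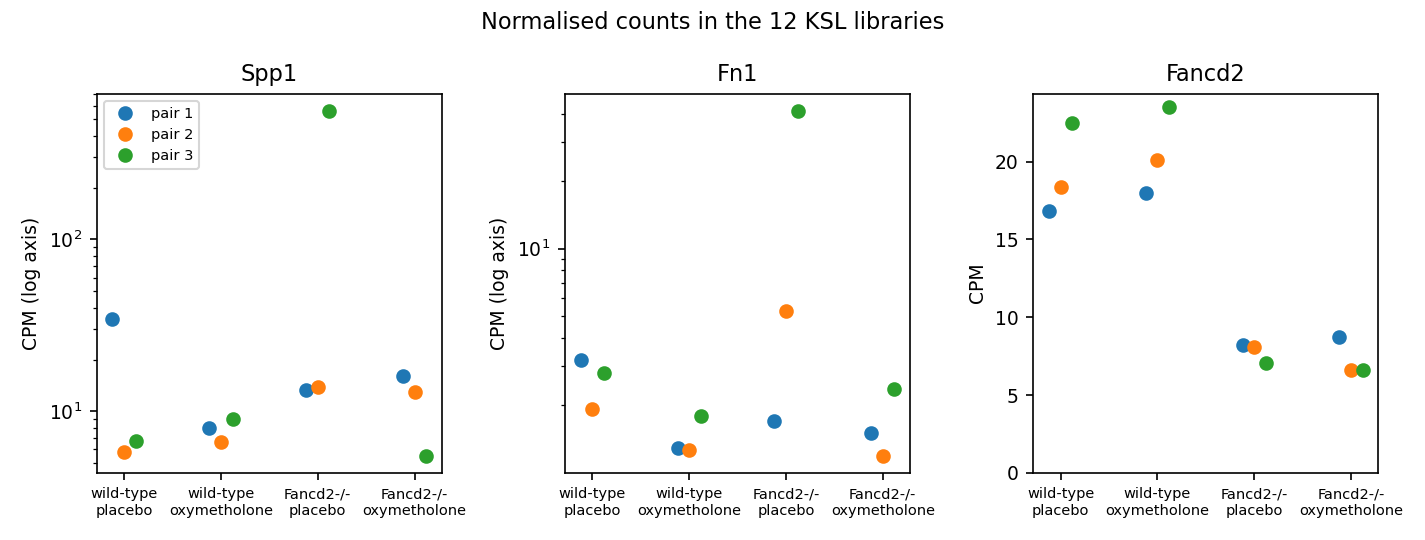
Normalised counts (CPM, vertical axis) of Spp1 and Fn1 (log axes) and Fancd2 (linear axis) in the 12 KSL libraries by group. Each point is a library coloured by pair, and Fancd2-/- placebo 3 has 561 CPM of Spp1.

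By lists, interferon response genes fell with oxymetholone in Fancd2-/- KSL cells (median log2 -0.20, 23 of 25 below 0, camera adjusted p = 4.5e-05, adjusted p = 0.566 with an estimated correlation), by -0.11, -0.30 and -0.18 in pairs 1 to 3. Neutrophil granule genes fell (-1.13, camera adjusted p = 4.8e-05), but by -2.28 in pair 2 against -0.19 and -0.08 in the others. B cell genes fell (-0.46, camera adjusted p = 0.000511), as did monocyte genes (-0.22, 0.00902), DNA replication (-0.12, 0.0053), mitosis (-0.18, 0.00641), oxidative stress (-0.13, 0.00887) and ribosomal protein genes (-0.11, 0.00953). In pairs 1 to 3 oxidative stress genes were at -0.03, 0.006 and -0.343. Ribosomal protein genes were at -0.067, 0.028 and -0.334, so both lists fell mainly in pair 3. Mitosis (0.042), DNA replication (0.018) and B cell genes (0.039) were above 0 in pair 1. Stem cell genes rose (0.15, camera adjusted p = 0.0053), with TGF-beta signalling (0.13, 0.00702), cell cycle inhibitors (0.18, 0.00898) and megakaryocyte genes (0.20, 0.00948). In pairs 1 to 3 stem cell genes were at 0.002, 0.111 and 0.264, and TGF-beta genes at 0.03, -0.022 and 0.408. Cell cycle inhibitors were at 0.045, 0.112 and 0.199, and megakaryocyte genes at -0.034, 0.199 and 0.453. Each rise was largest in pair 3, whose placebo library stood apart. The oxymetholone library of pair 3 was unlike the others too. On the second principal component it was at -18, its partner at -8.4 and the libraries of Fancd2-/- pairs 1 and 2 at 14.5 to 31.2. It held 113 M counted reads against 32.1 M in its partner. None of these 12 lists was kept with an estimated correlation (mitosis adjusted p = 0.593), and 4 of them were called without Fancd2-/- placebo 3 and its partner. Among mitosis genes the members that passed when adjusted over the list alone, Cenpf (0.49) and Mki67 (0.40), were higher, against the list median. Both are long transcripts (11137 and 10075 bases), and long transcripts were low in Fancd2-/- placebo 3.

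The other 14 lists did not pass camera in Fancd2-/- KSL cells: steroid receptor targets (median 0.10, adjusted p = 0.911), telomerase and shelterin (-0.04, adjusted p = 0.524), niche adhesion (-0.01, adjusted p = 0.911), lymphoid-primed genes (-0.04, adjusted p = 0.911), the Fanconi pathway (0.04, adjusted p = 0.333), p53 targets (0.00, adjusted p = 0.571), TNF response (0.05, adjusted p = 0.911), immediate early genes (0.08, adjusted p = 0.911), heme synthesis (0.00, adjusted p = 0.571), erythroid genes (-0.20, adjusted p = 0.203), T and NK cell genes (-0.53, adjusted p = 0.0663), mast cell genes (0.28, adjusted p = 0.223) and stromal genes (-0.38, adjusted p = 0.0568). Osteopontin and its receptors had a median of 0.08 and a mean of -0.09 (camera adjusted p = 0.681), the sign of the mean set by Spp1.

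In wild-type KSL cells oxymetholone changed 0 of 13259 genes by edgeR (356 with unadjusted p under 0.05 against 663 by chance), while DESeq2 called 4 and limma voom 247. Closest was Ctsg (NM_007800, chr14:56718718-56721411), the neutrophil protease cathepsin G, at 56.2 against 29.7 CPM (log2 0.92 ± 0.12, edgeR adjusted p = 0.0566). Next in the ranking upward were the kinetochore genes Cenpe (0.60) and Cenpf (0.57), Mki67 (0.47) and the basophil protease gene Mcpt8 (0.91), and downward Tcf15 (-0.76), the chemokine gene Cxcl10 (-1.69, adjusted p = 0.548), Slfn2 (-0.80), Gbp4 (-1.17) and Sc4mol (-0.56). The rule of 1.5-fold the same way in 3 of 3 pairs held for 23 genes. With the labels of pair 1, 2 or 3 swapped it held for 4, 7 and 5 (mean 5.33). These arrangements are too few to exclude chance. The 19 lower genes included Cpe and Ngp, which among wild-type KSL libraries were highest in placebo 1 (3.67 CPM) and placebo 3 (14.5 CPM). In Fancd2-/- cells the rule also held for 23, against a mean of 24.7.

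Mitosis genes rose as a group with oxymetholone in wild-type KSL cells (median log2 0.34, 25 of 25 above 0, camera adjusted p = 2.6e-32, adjusted p = 0.333 with an estimated correlation), by 0.50, 0.18 and 0.32 in pairs 1 to 3, with 13 members passing when adjusted over the list alone and 0 over all genes. DNA replication genes rose too (0.14, camera adjusted p = 1.44e-07, adjusted p = 0.453 with an estimated correlation), as did the Fanconi pathway (0.11, camera adjusted p = 0.00478) and mast cell and basophil genes (0.87, camera adjusted p = 0.000338, 4 adjusted over the list alone). Interferon response genes fell (-0.22, camera adjusted p = 1.35e-06, adjusted p = 0.479 with an estimated correlation), mainly in pair 2 (-0.58, against -0.01 and -0.05). Stem cell genes (-0.08, camera adjusted p = 5.82e-05), erythroid genes (-0.47, 5.34e-06), B cell genes (-0.29, 0.00238) and TNF response genes (-0.07, 0.0128) also fell. In pair 2 erythroid genes (0.22, against -0.84 and -0.79 in pairs 1 and 3) and B cell genes (0.26, against -0.98 and -0.38) went the other way. All 9 calls were lost with an estimated correlation.

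The oxymetholone effect on cell cycle lists differed between genotypes. Mitosis genes had a lower effect in Fancd2-/- than in wild-type cells (median difference -0.50, 25 of 25 below 0, camera adjusted p = 2.12e-22, adjusted p = 0.461 with an estimated correlation), with 15 members passing when adjusted over the list alone. The single-gene test called 0 of 13259 (458 with unadjusted p under 0.05, smallest adjusted p = 0.953 in edgeR), and DESeq2 called 1. The ranking held Tcf15 (1.0), Vwf, the von Willebrand factor gene (0.83), Tbkbp1 (0.72), Tnni3 (0.90) and BC005561 (0.61) upward, and Ctsg (-0.90), Kif2c (-0.75), Nup93 (-0.68), Ube2c (-0.76) and Ccnb1 (-0.77) downward. In simulated counts only 29.2% of 2-fold changes were found by this test.

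**Figure D3:**
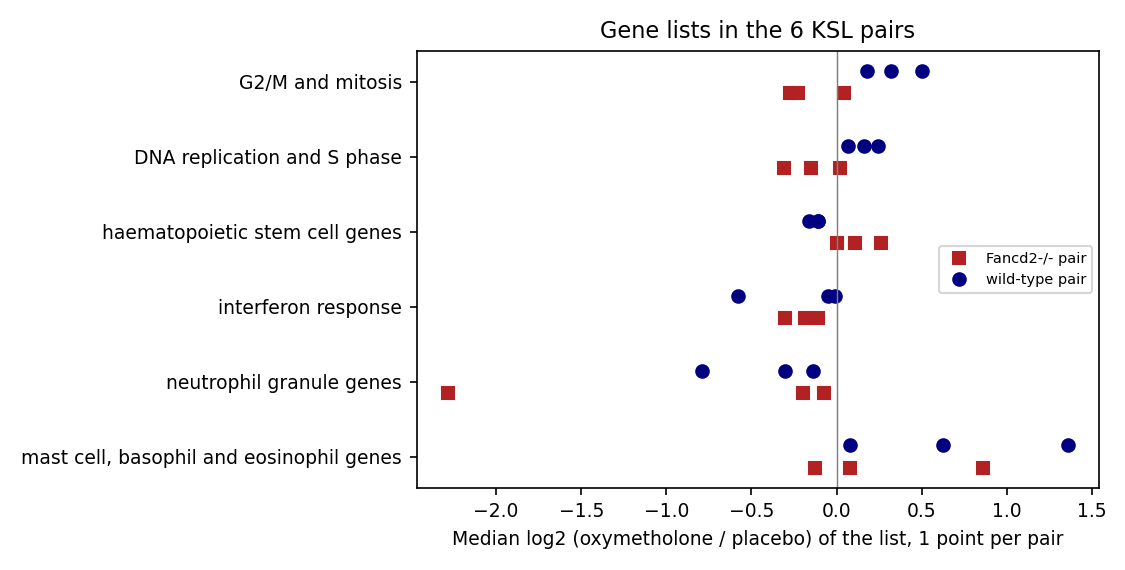
Median log2 ratio of oxymetholone over placebo (horizontal axis) of 6 gene lists in each of the 6 KSL pairs. Blue circles are wild-type and red squares Fancd2-/- pairs, and mitosis genes were at 0.503, 0.177 and 0.319 in wild-type pairs.

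Averaged over both genotypes, oxymetholone changed 0 of 13259 genes in KSL cells by edgeR (720 with unadjusted p under 0.05, smallest adjusted p = 0.331), while DESeq2 called 13 and limma voom 11. Highest in the ranking were Cenpf (NM_001081363, chr1:191464493-191511965, log2 0.53 ± 0.09) and Mki67 (NM_001081117, chr7:142881471-142908062, 0.44 ± 0.08), both transcribed in dividing cells, with Cenpe (0.43), Cep290 (0.47) and Mcpt8 (0.61), each higher in 6 of 6 pairs. Mki67, Cenpf, Cenpe and Cep290 are long transcripts (7813 to 11137 bases). They also parted 2 sets of erythroblast libraries that crossed the diets and were drawn by their slope on transcript length. With the length and GC trends removed they were at 0.35, 0.39, 0.32 and 0.28. Cxcl10 (NM_021274, chr5:92775667-92777880, -1.21), Oasl2 (-0.59), Lcn2 (-1.60), S100a9 (-1.02) and Apbb1 (-0.46) were lower in 6 of 6 pairs. Interferon response genes fell as a group (median -0.21, 24 of 25 below 0, camera adjusted p = 2.06e-09, adjusted p = 0.499 with an estimated correlation, 3 lower adjusted over the list alone). Lost with an estimated correlation were also B cell (-0.36, camera adjusted p = 7.01e-06), neutrophil (-1.02, 0.000203), erythroid (-0.25, 0.000454), monocyte (-0.22, 0.0131), mitosis (0.08, 1.53e-05), mast cell (0.42, 0.00325), Fanconi pathway (0.03, 0.0201) and TGF-beta genes (0.08, 0.039). The falls of mature blood cell genes were largest in Fancd2-/- pair 2 (neutrophil -2.28, B cell -1.17, erythroid -1.79), whose placebo library carried their transcripts (Hba-a1 113 CPM, Ngp 58.1 CPM), and this bears on Lcn2 and S100a9 too.

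Across genes, which are not independent replicates, the oxymetholone effects of the genotypes correlated weakly (r = 0.202, rho = 0.087, 52.3% with the same sign, r = 0.254 without the pair block). The oxymetholone effect in Fancd2-/- cells ran against the genotype effect on placebo (r = -0.579, rho = -0.537), but both contain the same placebo libraries, and unchanged groups sharing them gave r = -0.513. The covariance was -0.12 against -0.052 simulated, and 28.1% of genes had the same sign against 33.3% simulated. Among genes of at least 10 CPM the covariance was -0.039 against -0.018. Without Fancd2-/- placebo 3, which stood apart, r was -0.512 and the covariance -0.101, with the same sign for 32.3% of genes. With any other library of these groups left out r ran from -0.717 to -0.555. The simulation drew genes independently and was not repeated with a library left out. A reversal beyond the effect of the shared libraries was therefore not established. Of the 170 genes called on placebo 142 moved the other way with oxymetholone, which the shared libraries also favour.

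In wild-type erythroblasts oxymetholone changed 0 of 9694 genes by edgeR (123 with unadjusted p under 0.05 against 485 by chance, smallest adjusted p = 0.999), and DESeq2 and limma voom called 0 as well. The ranking held Fam101b (log2 0.86), Rnf157 (0.77), Zfp64 (0.62), Plag1 (0.46) and A830010M20Rik (0.33) upward, and Osbpl7 (-1.13), Crtc1 (-0.38), the transcription factor gene Zbtb7b (-0.47), Sepw1 (-0.27) and Igfn1 (-0.37) downward. By lists, mitosis genes were slightly higher (median 0.06, 24 of 25 above 0, camera adjusted p = 5.96e-05, adjusted p = 0.759 with an estimated correlation), neutrophil genes higher (0.21, camera adjusted p = 0.000405) and monocyte genes lower (-0.25, camera adjusted p = 0.00546). None of the 3 was kept with an estimated correlation. In simulated counts 89.2% of 2-fold changes were found in these cells.

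Erythroblasts differed from KSL cells in 11404 of 12538 genes on placebo, 4665 higher and 6739 lower (2440 and 9159 on the scaled matrix). The transferrin receptor gene Tfrc (log2 8.17), the cyclin E gene Ccne1 (6.36), Rrm2 (6.29) and Gclc (3.93) were higher. Cd34 (NM_001111059, chr1:196765015-196787486) was at 0.0592 against 780 CPM (-13.67), Kit at 0.435 against 416 CPM (-9.91), and Eltd1 (-12.37), Flt3 (-12.03), Gata2 (-9.99), Vim (-6.63) and Spp1 (-8.30, edgeR adjusted p = 0.0183) were lower. The Spp1 call was lost without any of the 3 placebo erythroblast libraries (-7.85, -7.71 and -12.19). By lists, medians were 11.92 for erythroid genes (23 of 23 called), 5.87 for heme synthesis, 3.92 for mitosis, 2.67 for DNA replication, 2.02 for the Fanconi pathway and 0.81 for oxidative stress. They were -8.85 for stem cell genes (21 called lower), -7.32 for lymphoid-primed genes, -4.60 for TNF response, -3.02 for TGF-beta signalling and -1.26 for ribosomal protein genes. camera called these 11 lists (adjusted p = 1.3e-09 for erythroid genes, adjusted p = 0.273 with an estimated correlation), and none was kept with an estimated correlation.

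The oxymetholone effect differed between wild-type erythroblasts and KSL cells for 2 of 12863 genes. Tmem56, a membrane protein gene (NM_178936, chr3:120904928-120966234), had a difference of 2.02 ± 0.26 (edgeR adjusted p = 0.00609), from 0.756 to 0.98 CPM on placebo and 0.2 to 0.245 CPM on oxymetholone in KSL cells, with 195 to 256 CPM in erythroblasts. Gfap, an intermediate filament gene (NM_010277, chr11:102748650-102758514), had 1.26 ± 0.19 (adjusted p = 0.0345), from 0.723 to 0.98 CPM on placebo and 0.343 to 0.398 CPM on oxymetholone in KSL cells. By lists, mitosis genes had a lower effect in erythroblasts (median -0.23, camera adjusted p = 2.07e-10, adjusted p = 0.391 with an estimated correlation), as had DNA replication genes (-0.12, camera adjusted p = 3.15e-05), and erythroid (0.31, 3.13e-06) and neutrophil genes (0.72, 2.38e-05) a higher one. None of these 4 lists was kept with an estimated correlation.

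In whole bone marrow, with 1 library per genotype and no replicate check, 40 of 11819 genes differed 2-fold or more, 15 higher and 25 lower in the Fancd2-/- library. Higher were the protease gene Adamts1 (ratio 4.39, counting interval 3.03 to 6.52), Cd209f (4.26), Cyr61 (3.84), the near-identical heat shock genes Hspa1a (3.83) and Hspa1b (3.75), Pla2g2d (2.75) and Cd8b1 (2.71). Higher in the wild-type library were Slc25a31 (5.58, 3.76 to 8.55), Trib3 (4.09), Fancd2 (3.68), Podxl (3.13), the interferon-induced Tgtp2 (2.98), Vcan (2.77), Ces1d (2.76), Tnni1 (2.43) and H2-Q7 (2.35). Spp1 was at 19 CPM in the Fancd2-/- and 14.1 CPM in the wild-type library (ratio 1.34, 1.26 to 1.44). Interferon response genes were lower (median log2 -0.52, 24 of 25 below 0, percentile 0 among random lists, 95% of which lay from -0.06 to 0.05), as were heme (-0.12) and erythroid genes (-0.11), and T and NK cell (0.22), monocyte (0.17), immediate early (0.16), steroid receptor target (0.13) and p53 target genes (0.11) were higher (percentile 100), followed by osteopontin and its receptors (0.12, percentile 99.8), stromal (0.13, 99.7) and TGF-beta genes (0.09, 99.7). DNA replication genes were lower (-0.07, percentile 0.18). Mitosis genes were at -0.02 (percentile 28.6). The counting intervals and percentiles leave out variation between marrow samples, and the random lists ignore correlation between the members of a list. These differences therefore could not be assigned to genotype.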

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

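The tests of the difference between populations and genotypes were planned, and the 40 splits for Tmem56 and Gfap and the test of erythroblast RNA were chosen after the result was seen. Tmem56 (2.02) and Gfap (1.26) were the only genes that the main edgeR fit called for a different oxymetholone effect in erythroblasts and KSL cells. Both were under 1 CPM in KSL cells, at 3 to 120 counts per library for Tmem56. limma voom called neither (its 1 call was another gene) and the scaled matrix called 0 genes, and the count was 0 without wild-type oxymetholone KSL 2 or wild-type placebo KSL 2. It was 1 without oxymetholone KSL 3, placebo KSL 1, oxymetholone erythroblast 1 or 2, or any placebo erythroblast library. Of 40 splits 10 called as many genes (highest other 290), but 6 of the other splits kept the diet groups of the KSL libraries, in which these genes differ, and 4 of those 6 called as many. Of the 33 that regrouped the KSL libraries 5 did, so chance could not be excluded, and the 290 point to a structure of the samples. RNA of erythroblasts in the placebo KSL libraries was tested as a source of Tmem56. Its levels would need 0.238, 0.366 and 0.333% of such RNA in pairs 1 to 3, but the 23 other transcripts abundant in erythroblasts fell by a median of only 0.061, 0.001 and 0.103 of what these shares would bring, which argued against it. Hba-a1, at 11810 to 14100 CPM in erythroblasts, fell by 1.84, 0.564 and 24.3 CPM where 30.3, 46.7 and 42.5 CPM were needed.

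With oxymetholone, 8 lists differed between Fancd2-/- and wild-type KSL cells (planned test), and none was kept with an estimated correlation. Mitosis genes (median difference -0.50), DNA replication genes (-0.26), oxidative stress genes (-0.15, camera adjusted p = 0.0198) and neutrophil genes (-0.40, camera adjusted p = 0.0101) had the lower effect in Fancd2-/- cells. Stem cell genes (0.28, camera adjusted p = 3.32e-07), megakaryocyte genes (0.29, camera adjusted p = 0.00988), cell cycle inhibitors (0.17, camera adjusted p = 0.0445) and TGF-beta genes (0.08, camera adjusted p = 0.0445) had the higher one. Mitosis genes were at 0.042, -0.227 and -0.276 in Fancd2-/- pairs and 0.503, 0.177 and 0.319 in wild-type pairs, so no pair of a genotype overlapped the other genotype. Without Fancd2-/- placebo 3 and its partner 6 lists were called, 4 of them among the 8. Of 10 splits only the real one gave a mitosis median as far from 0 as -0.498 (highest other 0.416), and 10 are too few for a share under 0.05. For single genes 10 of 10 called as many as the real 0 (highest other 1), as any split must.

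The rise of mitosis genes averaged over KSL pairs (median 0.079) was weighed against technical causes with planned tests, and the tests with the trends of each library removed were chosen after the result was seen. With the trend of the log2 change on length and GC over all other genes removed the median was 0.117. With the trends of each library removed it was 0.086, and 0.339 in wild-type pairs, which speaks against such a bias. Of 4 pairs above 0 the oxymetholone library was the deeper in 1, which leaves depth open. Of 32 swaps of labels within pairs 21 gave a median as far from 0 (highest other 0.249), so chance could not be excluded for the average.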

How the results depend on the processing

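Removing the low-count filter gave 16 calls for oxymetholone in Fancd2-/- KSL cells, 1 in wild-type and 20 in the average, against 0 each. The rule of 3 pairs gave 23 in either genotype, median-of-ratios factors 1 and the 6 wild-type libraries alone 1 in wild-type cells. DESeq2 gave 4 in wild-type cells, 1 in the interaction, 13 in the average, 815 between genotypes on placebo (170) and 86 on oxymetholone (17), and limma voom 247 in wild-type cells, 11 in the average, 1468, 47, and 1 between populations (2). The scaled matrix gave 0 there. Alternatives chosen after the data were seen gave 374 on placebo with the length and GC trends removed and 28 on oxymetholone with all RefSeq entries. Of 71 list calls by camera 1 was kept with an estimated correlation. That setting lost even the erythroid genes between erythroblasts and KSL cells, so a loss under it does not show that a list was unchanged. A call with the preset correlation alone does not show a change either. Over all lists, and counted apart from the 71, fry called 27. These were 23 between erythroblasts and KSL cells on placebo, 4 between genotypes on placebo, and 0 in every other comparison. Fits without the pair block changed no count more than 1.5-fold, and r of the shared effect was 0.254 (0.202), but Spp1 moved to -4.135 in Fancd2-/- cells (-1.678), -1.023 in wild-type cells (-0.554) and -3.112 in the interaction (-1.124). Reversed were Spp1 without pair 3 in Fancd2-/- cells (0.086, and 0.618 in the interaction), without pair 1 in wild-type cells (0.284), and between genotypes without Fancd2-/- placebo 3 (-0.197), and Fancd2 between populations without wild-type KSL oxymetholone 3 (0.054) or placebo 1 (0.058), and without erythroblast oxymetholone 3 (0.002) or placebo 2 (0.001). With a library or pair left out, counts were 0–12 for Fancd2-/- (12 without pair 1 or pair 2), 0–0 for wild-type, 0–0 for the interaction, 0–14 for the average (12 without Fancd2-/- pair 1, 13 without pair 2, 13 without wild-type pair 2 and 14 without pair 3), 19–236 on placebo, 2–8 on oxymetholone, 0–0 in erythroblasts, 11346–11536 and 0–2 between populations. The shared r was 0.122–0.446 and the r with genotype -0.717 to -0.512. The cause of these shifts was not tested. With a library or pair left out the reversed results ranged -3.528–0.086, -2.986–0.618, -1.006–0.284 and -0.197–5.02 for Spp1 in that order and -0.105–0.058 for Fancd2. Of 2072 gene values 1874 stayed, 136 were weaker, 54 stronger and 8 reversed. Depth limits the shallowest KSL library (10.8 M), and differences in the interaction below 4-fold were often out of reach (29.2% found at 2-fold).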

Other observations

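Spp1 in Fancd2-/- placebo 3 was weighed with planned tests, and the test with fibroblast genes was chosen after the result was seen. That library also had Fn1 at 41.2 CPM (at most 5.28 elsewhere in KSL cells), Sparc at 44.3, Col1a1 at 12.3 (at most 1.04), Cpe at 59.8 (at most 3.67) and Tnc at 31.6 CPM (at most 1.51), genes of matrix-producing cells. RNA of mesenchymal cells is a possible explanation: over the other Fancd2-/- placebo libraries the fibroblast genes had a median log2 ratio of 0.907 (6 of 13 at 1 or more, against 4.14% of all genes), and the stromal list 0.711 (6 of 12). The monocyte and macrophage list had 0.097 (1 of 16), and neither list decided the question. Fancd2 at 7.06 CPM argued against a mislabelled genotype. Against RNA of mesenchymal cells, the cKit+ Sca1+ Lin- gate of 2 sorts would be expected to remove such cells already. No stromal marker was part of that gate. Next highest in Spp1 (34.2 CPM), Cpe, Tnc and Col1a1, though not in Fn1 or Sparc, was wild-type placebo 1. It also had the next lowest slope on transcript length (-0.045). These 2 libraries share a title prefix that no other library has. Their oxymetholone partners are titled otherwise, so in both pairs the prefix cannot be told apart from diet. Another prefix is shared by wild-type oxymetholone 3, wild-type placebo 3 and Fancd2-/- oxymetholone 1. The placebo partner of Fancd2-/- oxymetholone 1 is titled otherwise, so that pair has the same limit. What the prefixes stand for was not traced.

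The genotype difference on placebo was weighed with planned tests, and the test of genes no longer called without Fancd2-/- placebo 3, the length and GC test, the test in pairs left out and the splits of the other comparisons were chosen after the result was seen. Without Fancd2-/- placebo 3, 62 of the 170 genes stayed called, which by the planned test left open whether that library carried the difference. All 24 named genes stayed called. Of the 108 genes no longer called 107 had the same sign in oxymetholone-fed mice, but these include the pair partner of that library, so this did not decide it. Leaving out other libraries also removed calls (32 of the 170 stayed without Fancd2-/- placebo 2, and 19 without wild-type placebo 1). Of the 24 named genes 19 stayed called without Fancd2-/- placebo 2, and 17, 20 and 18 without wild-type placebo 1, 2 and 3. With the length and GC trends removed 126 of the 170 genes stayed called, which argued against that bias. Of all 170, 99.4% had the same sign in oxymetholone-fed mice, which are pair partners of the placebo-fed ones (r within pairs -0.061 to 0.258 across genes), so chance and effects shared within pairs stayed open. For genes chosen without a pair of each genotype, the percent with the same sign in the oxymetholone-fed libraries of the pairs left out had a median of 87.1 and ran from 45.9 to 97.6 over 9 ways, lowest without Fancd2-/- pair 3 and wild-type pair 1, which did not exclude them either. Of 10 splits 1, the real one, called as many genes (highest other 0), and 10 splits are too few for a share under 0.05.

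Erythroblast libraries fell into 2 sets that crossed the diets, by tests chosen after the result was seen. The sets were drawn by the sign of each library's slope on transcript length. Genes higher in the set with more Mki67 had a median transcript length of 5099 bases, against 2793 for those lower and 3019 for all. The way the sets were drawn made this direction likely in advance, so it is no separate sign of a length effect. The mitosis list had a median of 0.02 with 8 of its 25 genes called. A difference in division was neither shown nor excluded. Mki67 was at 4395 to 4891 CPM in 3 libraries and 9400 to 10370 CPM in 3 others, and Cenpf at 304 to 365 and 735 to 816 CPM. Of 10 splits by diet label 10 called as many genes as the real 0, as any split must, and the 495 in the highest point to a structure of the samples. A term for 2 sets left the count at 0, and the cause was not tested. Erythroblast placebo 1 had Isg15 at 125 CPM (45.3 to 60 in the others).

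Fancd2-/- placebo 2 carried transcripts of mature blood cells, with Hba-a1 at 113 CPM and Ngp at 58.1 CPM against 1.84 to 2.33 and 5.96 to 6.63 CPM in the other Fancd2-/- placebo libraries. To a lesser degree wild-type placebo 3 did too, with Hba-a1 at 25 CPM and Ngp at 14.5 CPM. The other wild-type placebo libraries had 1.84 to 2.69 and 8.2 to 8.45 CPM. The splits below were chosen as tests after the result was seen. Where the real count is 0 every split calls as many, so such a test says nothing about chance. For oxymetholone in Fancd2-/- KSL cells 10 of 10 splits did, with 2662 in the highest. That split kept a pair together, so its contrast rested on pair 3, and splits that parted all 3 pairs called at most 1. In wild-type KSL cells 10 of 10 did (highest other 0), and between genotypes on oxymetholone 1 of 10, the real 17 (highest other 0). Between erythroblasts and KSL cells 1 of 10 did, the real 11404 (highest other 0), and 10 splits are too few for a share under 0.05 in each. Averaged over genotypes 32 of 32 swaps called as many as the real 0 (highest other 1), which decides nothing for the same reason.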
